A study of Mus musculus with 6 samples.

How the data were processed

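Total RNA of primary mouse keratinocytes was sequenced in 6 libraries as paired reads of 150 bp, per the labels' protocols. The deposited values are raw counts of reads per gene, in 1 table with a column for each library and unversioned Ensembl identifiers as rows. Per the submitters' processing notes, FastQC, STAR, HTSeq and DESeq2 were used with the builds mm39 and GRCm39. Tool versions, the annotation release and the strand setting of the counting are not given in the sources used here. The values are whole numbers whose sums differ between libraries, and nothing in the table was normalised. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. Near-identical copies can share reads, so values of Oas1a and Oas1g, Ifit3 and Ifit3b, the Sprr2 and Lce genes, Krt6a and Krt6b, Krt16 and Krt17, Hspa1a and Hspa1b, the H2 genes, Tnfrsf22 and Tnfrsf23, and the interferon alpha and lambda genes are uncertain.

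The table held 55416 genes, of which 28875 had at least 1 count in any library. Gene symbols were matched by identifier, and 52083 identifiers had one. The 3333 identifiers without a symbol took 0.369% to 0.546% of the counts of a library and stayed in the tests, since each is a gene. The annotation at hand, GENCODE M21, belongs to an older assembly than the one the authors used. It therefore served only for membership of the X and Y chromosomes and for the order of genes, and no positions are given. Every column of the table belonged to 1 of the 6 libraries.

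Libraries were grouped by the genotype in their labels, as 3 wild type libraries (numbered 1, 2 and 3) and 3 Cebpb knockout libraries (numbered 4, 5 and 6). The labels do not say whether the libraries of a genotype came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Within the wild type group, pairs of libraries differed by a chi-square of 30.3 to 46.9 per degree of freedom over genes with a mean of at least 50 counts. The range was 19.7 to 26.8 within the knockout group and 548.1 to 605.7 between genotypes. No pair was alike within sampling noise, so none was treated as a repeat of another. Libraries of 1 pool of cells would exceed that noise too, so this says nothing on whether they are separate cultures. The first principal component of log2 CPM held 88.2% of the variance.

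The main test was edgeR's quasi-likelihood test with robust dispersion (edgeR 4.0.16, R 4.3.3) on the deposited counts, with genotype as the only factor. Genes were filtered with filterByExpr at its minimum of 10 counts, which left 17659, and libraries were scaled by the trimmed mean of M values (TMM). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic. CPM values are TMM-scaled, and errors beside them are SDs over 3 libraries. The biological coefficient of variation was 0.109. Fold changes are knockout over wild type throughout. Where a library holds 3 counts or fewer of a gene, its level is given in CPM and no fold is printed. Intervals for single libraries were not needed, and such floors cover counting error only.

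Before the data were examined, 36 gene lists were written down for keratinocytes, UVB damage and other cell types that a culture of newborn epidermis could hold. They comprise 694 genes, 29 of them in more than 1 list. Lists with at least 5 tested members (34 lists) were compared with all other genes by limma's camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry were alternatives. With the preset correlation 22 lists were called, with an estimated correlation 0, and with fry 29. Fry asks whether the members of a list move one way on balance, and does not compare them with other genes. Counts of called members are given over all genes tested. Counts "adjusted over the list alone" were equal except in 8 lists, where they are printed beside the others.

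The genes named in the text were chosen by a rule also written before the data were examined. It takes the tested members of the C/EBP family. It adds the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 2 CPM over all libraries and no overlap between the groups. Further, it takes the 4 members with the smallest p of each primary list (interferon, TNF, p53 and apoptosis lists), and the 2 with the smallest p of each secondary list with a call. Tnf, Ifnb1, Cdkn1a, Mdm2, Fas, Krt5 and Krt10 were named whatever their values. Some genes that the rule takes are not reported here. Markers of other cell types and of sex stand outside that rule, and any gene said to be chosen after its values were seen does too.

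Alternatives were DESeq2 size factors, library totals without TMM, no filter on low counts, a minimum mean of 1 CPM, the tests of DESeq2 (version 1.42.0) and limma voom, removal of the 20 most abundant genes, stricter thresholds, and each library left out in turn. Thinning every library to the smallest total and leaving out genes of the X and Y chromosomes were added after the data were seen. The procedure was tested on simulated data for the same comparison, with 17306 genes, of which 200 were changed in both directions and 1 list was shifted together. EdgeR's quasi-likelihood test recovered 70.1% of changes of 0.5 log2 units, 94% of changes of 1 and 98.5% of changes of 2, with 4.42% of its calls false. False calls were 2.24% with limma voom and 9.47% with DESeq2. Nearly all simulated genes were unchanged, whereas 48.6% of the tested genes were called in the data. These shares therefore may not hold for the data, and the simulation does not test the choice of scaling. Beside the shifted list of the same simulation, camera with the preset correlation also called 1 of the unshifted lists, camera with an estimated correlation called 0 and fry 1.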

Results

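RNA was sequenced from primary mouse keratinocytes, the cells that build the epidermis, grown from the skin of wild type and Cebpb knockout pups 1 to 2 days old. The growth label names a hybrid strain background. Cebpb encodes C/EBPβ, a leucine zipper transcription factor. The cells were kept in 0.05 mM calcium, a low concentration that restrains terminal differentiation, and treated 5 days after plating. They received 10 mJ/cm2 of UVB from a 312 nm lamp and were collected 8 h later. The set holds 3 wild type and 3 knockout libraries, all irradiated, so the values describe differences between genotypes after UVB and not the response to UVB itself. Total counts were 120262861, 122797031 and 107757415 in the wild type libraries and 87360490, 92987497 and 81256192 in the knockout libraries, deep enough that 3 counts correspond to 0.0349 CPM or less in every library. The series title names apoptosis and the type I interferon (IFN) and TNF responses as the questions at hand.

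Cebpb (ENSMUSG00000056501) was nearly absent from the knockout libraries, with 78, 109 and 78 counts against 18184, 17628 and 12036 counts in the wild type libraries. Its level was 145 ± 21.9 CPM in wild type and 0.942 ± 0.143 CPM in knockout cells (SD, n = 3 each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, it fell by 7.26 ± 0.14 log2 units (SE, adjusted p = 1.51e-14). Of the other C/EBP family members tested, Cebpa (ENSMUSG00000034957) fell by 0.48, from 358 ± 33.5 to 258 ± 36.8 CPM, and Cebpg rose by 0.23 (edgeR adjusted p = 0.0124). The call of Cebpg was lost without wild type replicate 2 (0.16, adjusted p = 0.0745 by edgeR) and without knockout replicate 5 (0.21, 0.053) or 6 (0.21, 0.0526). Cebpd (log2 fold change 0.09, edgeR adjusted p = 0.404) and Ddit3 (0.20, edgeR adjusted p = 0.0732) were not called, and both were with library totals (0.29 and 0.40). Ddit3 was also called among genes with a mean of at least 1 CPM (0.22, edgeR adjusted p = 0.0431) and with libraries thinned to the smallest total, an alternative chosen after the data were seen (0.23, edgeR adjusted p = 0.0481). The list of 5 tested members held 1 called higher and 2 lower, or 2 and 2 adjusted over the list alone. Its median was 0.09, its mean -1.44 and its camera test downward (adjusted p = 8.9e-04, or adjusted p = 0.159 with an estimated correlation). The list holds the deleted Cebpb itself, so this mean and test restate the deletion, and the other 4 members lay between -0.48 and 0.23.

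Knockout and wild type libraries also differed in sex-linked transcripts. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 64.4 ± 3.71 CPM in wild type and 0.129 ± 0.0284 CPM in knockout cells (SD, n = 3 each). Ddx3y alone had 3655, 3657 and 3283 counts in the wild type libraries and 1, 3 and 6 in the knockout libraries. Xist, which is transcribed from the inactive X chromosome of females, was present in both, at 402 ± 14 and 587 ± 18.3 CPM. All wild type libraries thus carried transcripts of male and female cells, and the knockout libraries almost none of male cells. The make-up of the counts differed too, with no overlap between genotypes. Mitochondrial genes took 1.47% to 1.64% of the counts in wild type and 1.79% to 2.17% in knockout libraries, ribosomal protein genes 7.17% to 7.61% and 6.26% to 6.76%, and the 20 most abundant genes 13.0% to 13.6% and 10.4% to 10.7%. These differences run with genotype through every gene and gene group given here, the type I IFN, TNF and differentiation genes included.

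**Figure D1:**
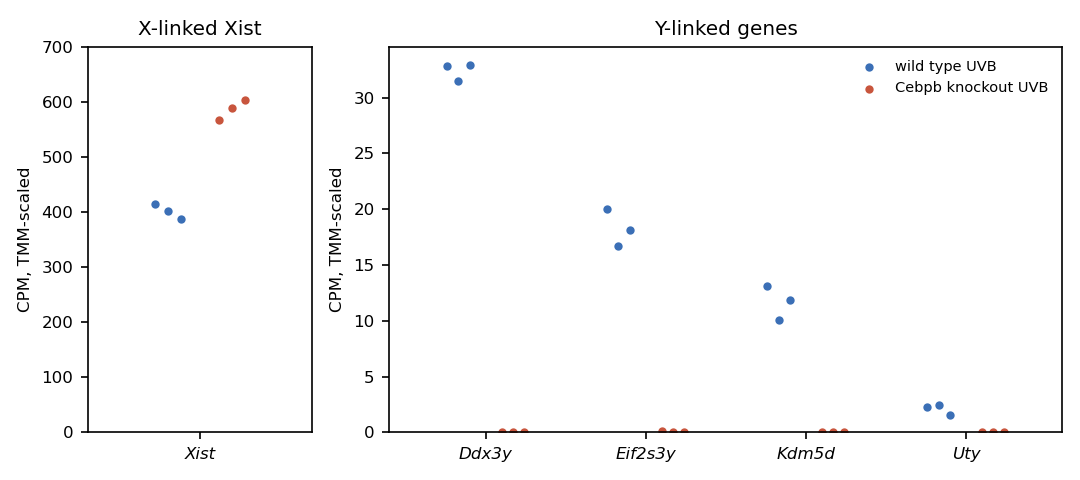
TMM-scaled CPM of the X-linked gene Xist (left) and of Y-linked genes (right) on linear axes, with 1 point for each of the 3 wild type (blue) and 3 knockout (red) libraries. Y-linked genes are near 0 in the knockout libraries, and Xist averages 402 CPM in wild type and 587 CPM in knockout libraries.

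Of the 17659 genes tested, 4387 were higher and 4192 lower in knockout cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The rises and falls reached at least 1 log2 unit in 1512 and 1049 genes, and at least 2 log2 units in 411 and 392. The largest rises named by the rule were those of Rgs4, an inhibitor of G protein signalling, from 0.168 ± 0.0934 to 13.7 ± 0.923 CPM, Add2 (5.33 ± 0.26 log2 units, SE), the microfibril gene Fbn1 (4.93 ± 0.28), and Lgr6 (4.60 ± 0.52), a receptor of follicle stem cells. Lgr6 had 4, 11 and 41 counts in the wild type libraries, and its log2 fold change was 5.98 without wild type replicate 3, above that of Add2, and 4.10 without wild type replicate 1. Entpd3 (4.53), Plekhb1 (4.42), Fbxo40 (4.32) and Dtx4 (4.21) followed. The deepest falls, besides Cebpb and the Y-linked Ddx3y, Kdm5d and Eif2s3y, were in Idi2, from 15.1 ± 1.3 to 0.0875 ± 0.0389 CPM, in Saa3, an acute-phase gene, from 5.86 ± 0.972 to 0.0489 ± 0.0421 CPM, in Tgm3, a transglutaminase of the cornified layer, which fell by 6.55, and in the protease inhibitor Slpi, which fell by 5.43. Groups did not overlap in 9953 genes (56.4%), where chance gives 10%. With library totals in place of TMM, which moves the median of all genes up by 0.20 log2 units, 6478 genes were called higher and 2452 lower, so the share of higher calls went from 51.1% to 72.5%. Without genes of the X and Y chromosomes, 4251 genes were higher and 4063 lower.

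**Figure D2:**
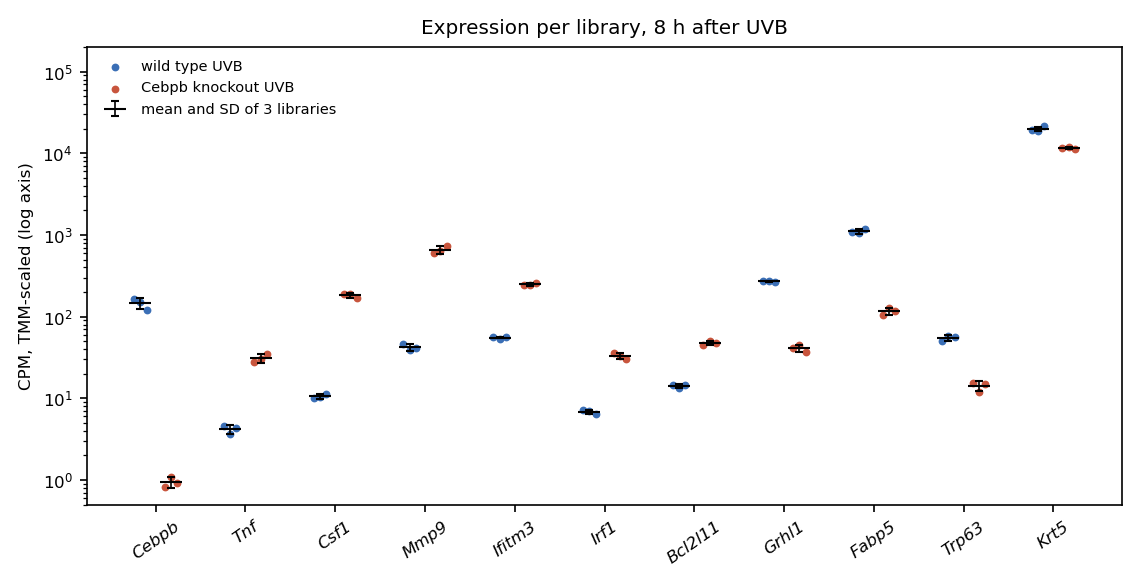
TMM-scaled CPM of named genes on a log axis, with 1 point for each of the 3 wild type (blue) and 3 knockout (red) libraries and black marks for the mean and SD. Tnf, Csf1, Mmp9, Ifitm3, Irf1 and Bcl2l11 are higher in knockout, and Cebpb, Grhl1, Fabp5, Trp63 and Krt5 lower, with no overlap between the groups.

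Genes of the type I IFN response were higher in knockout cells. Of 53 tested, 41 rose, 0 fell and 12 were not called, with a median log2 fold change of 1.08. The membrane protein gene Ifitm3 (ENSMUSG00000025492), which restricts viral entry, rose from 55.0 ± 1.06 to 249 ± 9.77 CPM (2.18 ± 0.06 log2 units, SE). Rigi, a sensor of viral RNA, rose by 1.83, Oasl2 by 2.00 and Bst2, which tethers virions, by 1.08. By limma's camera the list moved up against all other genes (adjusted p = 2.99e-15), which was not called with an estimated correlation (adjusted p = 0.226 with an estimated correlation). Counts adjusted over the list alone were 41 and 0. In the list of IFN production and signalling, 10 of 23 members rose, 3 fell and 10 were not called, in both adjustments (median 0.09, camera adjusted p = 0.0201, or adjusted p = 0.159 with an estimated correlation). The transcription factor gene Irf1 rose from 6.85 ± 0.428 to 33.2 ± 2.93 CPM, the kinase gene Ikbke by 1.32, Tyk2 by 0.71 and the RNA-editing gene Adar by 0.59. Ifnb1, which encodes interferon beta, stood at 0.551 ± 0.0547 CPM in wild type and 0.380 ± 0.0282 CPM in knockout cells and was not called (log2 fold change -0.53 ± 0.32, edgeR adjusted p = 0.189).

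TNF and NF-kB target genes were mostly higher in knockout cells. Of 37 tested, 29 rose, 3 fell and 5 were not called, also when adjusted over the list alone, with a median log2 fold change of 1.11. Csf1 (ENSMUSG00000014599), a growth factor of macrophages, rose from 10.6 ± 0.742 to 182 ± 12.8 CPM (4.10 ± 0.08 log2 units, SE), and the gelatinase gene Mmp9 from 42.0 ± 3.83 to 657 ± 66.7 CPM (3.97 ± 0.09). The cytokine gene Lif rose by 2.55 and the neutrophil chemokine gene Cxcl5 by 3.29. The list moved up by limma's camera (adjusted p = 3.84e-20), and missed the threshold with adjusted p = 0.0581 with an estimated correlation. Tnf itself (ENSMUSG00000024401) rose from 4.19 ± 0.503 to 30.9 ± 3.52 CPM (2.88 ± 0.12 log2 units, edgeR adjusted p = 1.49e-11, n = 3 each). Among TNF superfamily ligands, receptors and death signalling genes, 14 of 27 rose, 3 fell and 10 were not called, in both adjustments, with a median of 0.31. Casp8, the initiator caspase of death receptors, rose by 1.09, the deubiquitinase gene Cyld by 1.25 and the death receptor gene Fas by 0.63, whereas Tnfrsf21 fell by 1.71. Camera called the list up (adjusted p = 0.00634, or adjusted p = 0.102 with an estimated correlation).

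Apoptosis genes moved in both directions. Of 36 tested, 22 rose, 7 fell and 7 were not called, or 22 and 8 adjusted over the list alone. Bcl2l11, which encodes the death promoter BIM, rose from 14.2 ± 0.686 to 47.4 ± 3.08 CPM (1.74 ± 0.08 log2 units, SE). Bnip3, a mitochondrial gene of the BCL2 family that is induced by low oxygen, fell by 3.22 and Bok by 1.22. The median was 0.38 and camera called the list up (adjusted p = 0.0031, or adjusted p = 0.0887 with an estimated correlation).

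Of 39 p53 target genes, 23 rose, 6 fell and 10 were not called, in both adjustments, with a median log2 fold change of 0.32 (camera adjusted p = 0.00548, or adjusted p = 0.434 with an estimated correlation). The spindle genes Ckap2 and Psrc1 rose by 2.00 and 0.92, while Perp, a desmosome gene, fell from 2955 ± 173 to 1513 ± 86.1 CPM, and the kinase gene Plk3 fell by 1.64. The cell cycle inhibitor Cdkn1a, at 1820 ± 225 CPM in wild type and 2012 ± 103 CPM in knockout cells, was not called (0.14 ± 0.08, edgeR adjusted p = 0.13), nor was Mdm2 (0.06 ± 0.06, edgeR adjusted p = 0.424). With library totals both were called higher (0.34 and 0.26), and Cdkn1a also was without wild type replicate 1 (0.24, edgeR adjusted p = 0.0105) and with no filter on low counts (0.14, edgeR adjusted p = 0.0319). Genes of nucleotide excision repair, which removes UVB photoproducts, were split, with 10 of 34 higher, 15 lower and 9 not called, or 10 and 17 adjusted over the list alone. Their median was -0.14 with TMM and 0.06 with library totals, and camera did not call the list (adjusted p = 0.688). The replicative polymerase gene Pole rose by 1.05, and Polh, whose product copies past UV lesions, fell by 1.05.

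Every one of the 48 epidermal differentiation genes tested was lower in knockout cells, with 45 of them lower under library totals too. Their median log2 fold change was -2.04 (camera adjusted p = 6.08e-51, or adjusted p = 0.0736 with an estimated correlation), and all 48 were also lower adjusted over the list alone. Grhl1 (ENSMUSG00000020656), a transcription factor gene of the epidermal barrier, fell from 270 ± 3.12 to 41.2 ± 4.02 CPM. Elovl4, needed for the very long fatty acids of the barrier, fell by 3.26 ± 0.09 log2 units. Krt10, an early differentiation keratin that is scarce here, stood at 6.13 ± 1.31 and 4.25 ± 0.19 CPM and fell by 0.53. Its call was lost with library totals (-0.33, edgeR adjusted p = 0.0885) and without wild type replicate 3 (-0.35, edgeR adjusted p = 0.0741). Stress keratins and antimicrobial genes had 16 of 18 lower, 1 higher and 1 not called (median -1.86, camera adjusted p = 6.2e-23, or adjusted p = 0.0695 with an estimated correlation). In that list S100a8 fell from 48.6 ± 6.55 to 2.75 ± 0.428 CPM and Lcn2 from 45.0 ± 3.05 to 6.47 ± 0.536 CPM.

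Basal keratinocyte genes moved apart, with 8 of 19 higher, 10 lower and 1 not called (median -0.28, camera adjusted p = 0.114). With no filter on low counts camera called this list down (-0.28, adjusted p = 0.041). Krt5 (ENSMUSG00000061527), the basal keratin, fell from 19820 ± 1260 to 11540 ± 275 CPM. Trp63, the transcription factor gene of stratified epithelia, fell by 1.95 ± 0.10 log2 units and Dst, a hemidesmosome gene, by 1.53. Inflammasome and pyroptosis genes had 2 of 13 higher, 6 lower and 5 not called, with a median of -0.05 that became 0.15 with library totals (camera adjusted p = 0.314). Gsdma, a pore-forming gasdermin of skin, fell by 2.37 and Nlrp10 rose by 1.41. For these lists, counts adjusted over the list alone were equal.

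**Figure D3:**
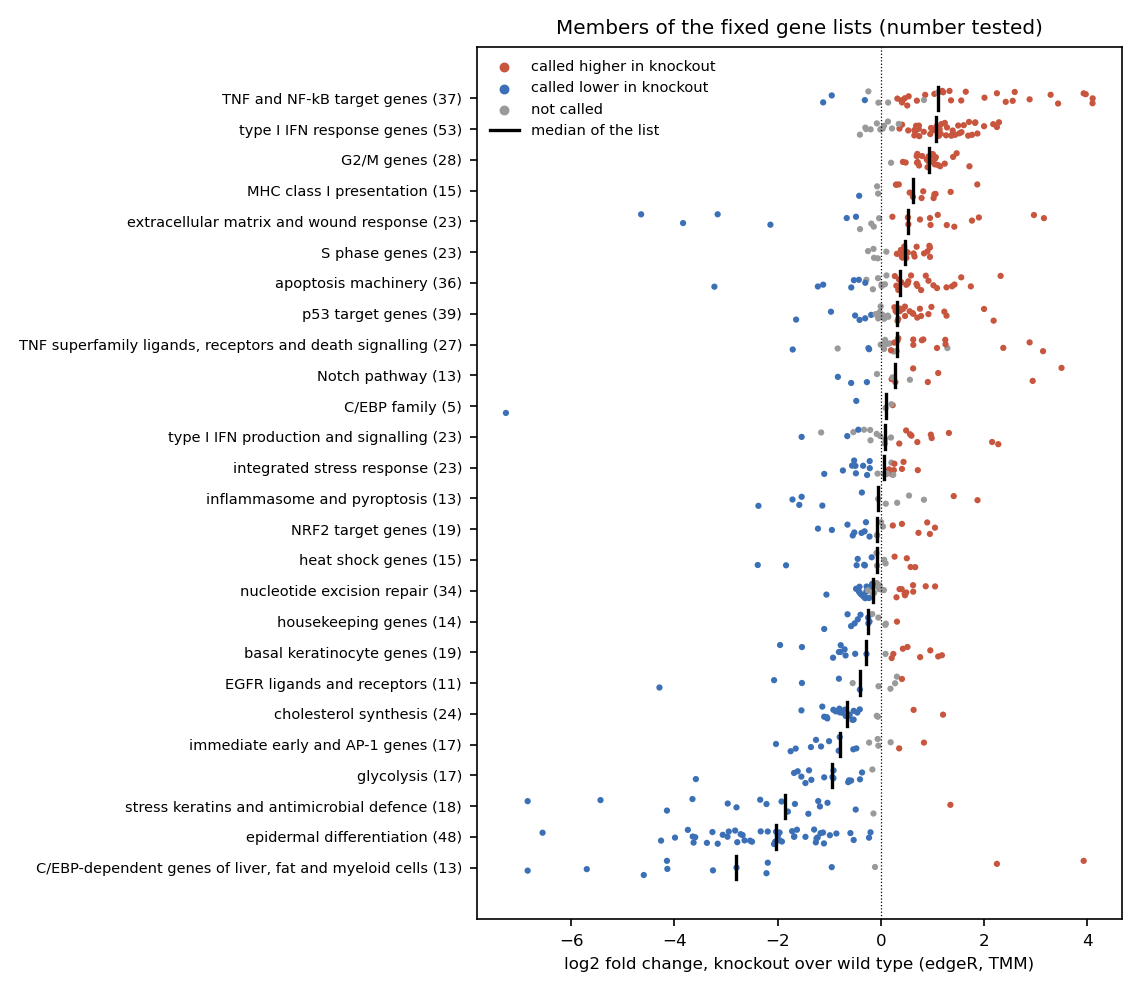
Log2 fold change, knockout over wild type, of every tested member of the fixed gene lists, other than the lists of markers of other cell types and of sex, with the number tested in parentheses, red and blue points for members called higher and lower, grey for members not called, and a black bar at each median. Medians run from -2.80 for C/EBP-dependent genes and -2.04 for epidermal differentiation to 1.08 for type I IFN response genes and 1.11 for TNF and NF-kB target genes.

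Cell cycle genes were higher in knockout cells. Of 28 G2/M genes, 27 rose and 1 was not called, in both adjustments (median 0.93, camera adjusted p = 2.29e-06, or adjusted p = 0.154 with an estimated correlation). The kinesin gene Kif23 rose by 1.72, from 1.78 ± 0.314 to 5.85 ± 0.576 CPM, and cyclin gene Ccnb1 by 1.05. Of 23 S phase genes, 18 rose, 0 fell and 5 were not called, or 18 and 2 adjusted over the list alone (median 0.46, camera adjusted p = 0.00245, or adjusted p = 0.369 with an estimated correlation). Mcm7, part of the replicative helicase, rose by 0.95.

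Genes that C/EBP factors regulate in liver, fat and myeloid cells had 10 of 13 lower, 2 higher and 1 not called in both adjustments (median -2.80, camera adjusted p = 6.49e-15, or adjusted p = 0.0695 with an estimated correlation). The fatty acid carrier gene Fabp5 (ENSMUSG00000027533) fell from 1102 ± 79.6 to 116 ± 12 CPM, and S100a8 and Lcn2, named above, belong here too. Of 17 immediate early and AP-1 genes, 11 fell, 2 rose and 4 were not called in both adjustments (median -0.80, camera adjusted p = 1.34e-05, or adjusted p = 0.365 with an estimated correlation). Myc fell from 70.2 ± 2.1 to 20.9 ± 0.662 CPM and Egr3 by 2.03. Of 11 EGFR ligands and receptors, 5 fell, 1 rose and 5 were not called (median -0.41, camera adjusted p = 0.0201, or adjusted p = 0.319 with an estimated correlation). The ligand gene Epgn fell from 202 ± 36 to 10.3 ± 2.08 CPM and the receptor gene Egfr by 0.81.

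Glycolysis and cholesterol synthesis genes were mostly lower in knockout cells. Of 17 glycolysis genes, 16 fell and 1 was not called, or 17 fell adjusted over the list alone (median -0.94, camera adjusted p = 9.72e-23, or adjusted p = 0.0581 with an estimated correlation). Slc16a3, a lactate exporter, fell from 61.5 ± 7.32 to 5.13 ± 0.0515 CPM and the phosphofructokinase gene Pfkl from 292 ± 0.684 to 95.7 ± 1.74 CPM. Of 24 genes of cholesterol synthesis, 20 fell, 2 rose and 2 were not called (median -0.66, camera adjusted p = 1.19e-11, or adjusted p = 0.154 with an estimated correlation). Lss, which makes lanosterol, fell by 1.54. NRF2 targets, part of the defence against oxidants, had 6 of 19 higher, 9 lower and 4 not called (camera adjusted p = 0.326), with a median of -0.07 that became 0.12 with library totals. Hmox1 fell by 1.22 and Srxn1 by 0.65. The integrated stress response had 7 of 23 higher, 10 lower and 6 not called, or 8 and 10 adjusted over the list alone. Its median was 0.06, its mean -0.08 and its camera test downward but not called (adjusted p = 0.481), and the test turned upward with library totals. Atf4 fell from 146 ± 5.01 to 88.0 ± 3.69 CPM and Ddit4 rose by 0.72.

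MHC class I presentation genes had 12 of 15 higher, 1 lower and 2 not called in both adjustments (median 0.62, camera adjusted p = 5.53e-06, or adjusted p = 0.102 with an estimated correlation). Tapbp, which loads peptides, rose from 128 ± 2.33 to 327 ± 6.36 CPM and H2-Q4 by 1.87. Extracellular matrix and wound genes had 13 of 23 higher, 6 lower and 4 not called, or 13 and 7 adjusted over the list alone (median 0.52, camera adjusted p = 0.00245, or adjusted p = 0.436 with an estimated correlation). Fibronectin, Fn1, rose from 114 ± 7.34 to 890 ± 73.8 CPM, and the protease inhibitor Timp3 fell from 147 ± 13.4 to 16.4 ± 1.05 CPM. In the Notch pathway 7 of 13 genes were higher, 3 lower and 3 not called (median 0.28, camera adjusted p = 0.114), with the ligand gene Jag1 up by 1.11 and Notch2 down (log2 fold change -0.83). Heat shock genes had 4 of 15 higher, 7 lower and 4 not called (camera adjusted p = 0.0206, or adjusted p = 0.154 with an estimated correlation). Their median was -0.08 with TMM and 0.11 with library totals, where the list was no longer called (adjusted p = 0.0878), nor was it among genes with a mean of at least 1 CPM (adjusted p = 0.0583). The small heat shock genes Cryab and Hspb1 fell by 2.38 and 1.84. Of 14 genes often used as references, 9 fell, 1 rose and 4 were not called (median -0.24, camera adjusted p = 0.00732, or adjusted p = 0.285 with an estimated correlation), led by the glycolytic genes Pgk1 (-1.10) and Gapdh (-0.58). With library totals that list was not called (-0.05, adjusted p = 0.0595), with 6 genes lower and 3 higher.

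Markers of other cell types moved in both directions. In the list of Merkel and simple epithelial markers, 5 of 8 rose, 1 fell and 2 were not called (median 0.51, camera adjusted p = 9.26e-09, or adjusted p = 0.0581 with an estimated correlation). Its simple epithelial keratins Krt8 and Krt18 rose from 60.5 ± 1.74 to 960 ± 59.4 CPM and from 62.9 ± 1.19 to 451 ± 57.2 CPM. Krt20, of Merkel cells, was at 0.524 ± 0.154 and 0.365 ± 0.134 CPM and was not called. Melanocyte markers had 7 of 10 lower and 3 not called, or 8 lower adjusted over the list alone (median -0.31, camera adjusted p = 0.089, or adjusted p = 0.0243 with no filter on low counts). Fibroblast markers had 3 of 8 lower and 5 not called (camera adjusted p = 0.377), and endothelial markers 1 of 5 higher, 1 lower and 3 not called (adjusted p = 0.852). Immune and Langerhans cell markers had 2 of 8 higher, 3 lower and 3 not called (camera adjusted p = 0.492), with large moves of single members in both directions. Hair follicle and sebaceous markers had 3 of 8 higher, Lgr6 among them, 4 lower and 1 not called, with a median of -0.58, a mean of 0.36 and a camera test downward but not called (adjusted p = 0.089, or called with adjusted p = 0.0354 with no filter on low counts). Schwann cell markers had 2 of 6 higher, 2 lower and 2 not called, with a median of 0.47 and a mean of 0.35 and a camera test downward but not called (adjusted p = 0.884). Of the muscle markers only Acta1 was tested, and it rose by 0.49. Of the erythroid markers 1 was tested and was not called. The list of 5 sex-linked genes had Xist higher and 4 Y-linked genes lower (camera adjusted p = 1.29e-19, or adjusted p = 0.0581 with an estimated correlation).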

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

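The thinned libraries and the removal of X and Y genes were chosen after the data were seen, and all other alternatives before. Of the 8579 genes called, as far as each alternative tested them, 98.5% kept their call and direction with DESeq2 size factors, 98.7% with the DESeq2 test, 98.8% with limma voom, 79.7% with library totals and 85.2% to 90.9% without any 1 library, and 0 were called in the opposite direction. Without 1 library each, 3781 to 4251 genes were higher and 3719 to 4071 lower. With a minimum of 1 log2 unit, 1512 were higher and 1049 lower, since fewer genes qualify. With library totals 2452 were lower, which goes with the shift of 0.20 in the median of all genes. With an estimated correlation, the medians being the same by construction, camera no longer called the type I IFN response genes (1.08, adjusted p = 0.226), TNF and NF-kB targets (1.11, 0.0581), p53 targets (0.32, 0.434) or apoptosis genes (0.38, 0.0887), and it called 0 of the other fixed lists in place of 18. With no filter on low counts it called 21 of these. The estimate was above the preset 0.01 for type I IFN response genes (0.4281), TNF and NF-kB targets (0.0835) and p53 targets (0.2264). For apoptosis genes it was -0.0224, yet the unadjusted camera p rose from 0.00146 to 0.0209. It was also below 0.01 in the TNF superfamily (-0.0133), heat shock (-0.0067) and Merkel (-0.0895) lists, which lost their calls too. A higher correlation cannot account for the lost calls of such lists. With an estimated correlation, camera also judges its statistic on the residual degrees of freedom of the 6 libraries, rather than on the number of genes. This raises the p-value of a given statistic at any correlation. How much of each lost call comes from it was not tested. With library totals, the direction of camera's test reversed for nucleotide excision repair (median -0.144, then 0.055) and the integrated stress response (0.065, then 0.26). Without wild type replicate 3 it reversed for Schwann cell markers (median 0.474, then 0.46, range 0.34 to 0.55 without 1 library each). The medians of the integrated stress response and Schwann lists kept their sign. None of these lists was called, and the cause was not tested. Cebpb kept its call throughout, between -7.39 and -7.17 without 1 library each. No paired analysis was possible because the libraries are numbered 1 to 6 and no number occurs in both genotypes. Thinning every library to 81256192 counts kept 97.9% of the calls tested there, and a gene under 3 counts, or 0.0258 to 0.0349 CPM by library, is not detectable at this depth.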

Other observations

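Of the tests in this part, those of the hypoxia-inducible list and of the neighbours of Cebpb were written down before their results were seen; all others, and the genes named here, were chosen after. Hypoxia-inducible genes, a list compiled after the fall of glycolysis genes was seen and sharing none of its genes with that list, had 13 of 23 members lower (56.5%), 3 higher and 7 not called, where 23.7% of all tested genes were lower. Ak4 fell from 64.8 ± 4.56 to 6.02 ± 1.36 CPM (n = 3 each), the carbonic anhydrase gene Car12 from 45.3 ± 5.83 to 5.02 ± 0.347 CPM and the peptide hormone gene Adm from 38.4 ± 9.38 to 7.71 ± 1.1 CPM, while the collagen crosslinker gene Loxl2 rose by 1.33. Limma's camera called the list down (adjusted p = 1.19e-05, or adjusted p = 0.188 with an estimated correlation), and 11 members were lower and 6 higher with library totals. The share of 56.5% lower met the prediction for a hypoxia-inducible programme that is lower in knockout cells, which may include the glycolysis genes. The fall covered only part of the list. Among the 7 members not called were Kdm3a (log2 fold change 0.12), Pfkfb4 (-0.07), Mxi1 (-0.09) and Hilpda (0.16). Oxygen, cell density and HIF protein were not measured.

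Imprinted genes, expressed from 1 parental allele, had 13 of 30 tested members lower, 9 higher and 8 not called (median -0.06, or 0.14 with library totals; camera adjusted p = 6.04e-04 downward, or adjusted p = 0.188 with an estimated correlation). Several abundant members fell: Peg3 from 667 ± 12.1 to 67.7 ± 5.38 CPM, Mest from 189 ± 12.2 to 32.1 ± 3.47 CPM, the cell cycle inhibitor Cdkn1c from 72.1 ± 2.81 to 16.2 ± 2.15 CPM, Plagl1 by 1.92 and H19 by 1.51. Igf2r and Grb10 rose by 0.46 and 0.91. Among 9 tested claudins of tight junctions, 4 rose, 2 fell and 3 were not called, with a median log2 fold change of 0.03. Camera called the list up (adjusted p = 1.19e-05, or adjusted p = 0.124 with an estimated correlation), and it was not run without the largest rises. Cldn6 rose from 2.37 ± 0.126 to 30.5 ± 2.26 CPM, Cldn7 from 9.83 ± 0.847 to 79.2 ± 3.74 CPM and Cldn3 by 2.01, while Cldn1, the main claudin of epidermis, fell by 1.03. Cldn4, the most abundant of the 9 in both genotypes, rose from 1558 ± 107 to 2502 ± 22.7 CPM.

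The first pattern to weigh is the sex make-up of the cultures, which runs with genotype in all 6 libraries. Taken from Xist, male cells would make up 31.6% of the wild type cultures. Removing them could then raise a gene of female cells by no more than the largest Xist difference between libraries, 1.56-fold, if Xist tracks the female share. That bound was exceeded by over 2 SE in 1438 called rises, among them 29 type I IFN response genes. It covers the absence of male cells only, and no other difference between the cultures. For the other 2949 rises, and for the 4192 falls apart from the deleted Cebpb and the Y-linked genes, genotype and sex make-up cannot be told apart, since no library separates them, although a 4-fold fall, reached by 392 genes, would need a level 10.5-fold higher in male than in female cells. A mislabelled library is argued against by Cebpb, whose highest knockout level was 0.91% of the lowest wild type level. The summed Y-linked level varied by 5.77% between the wild type libraries, which might come from 1 shared pool of cells, but the share of simulated sets of pups with as small a spread was 0.101, 0.042 and 0.021 for assumed sets of 4, 10 and 20 pups, so that stays open.

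The second pattern is the state of the keratinocytes, with 48 of 48 differentiation genes lower. Fewer differentiated cells among otherwise unaltered ones would leave basal genes level or higher, but 10 basal genes were lower with TMM and 9 with library totals, and 8 and 9 were higher. Dilution by another cell type would lower basal genes about as much as the differentiation genes, while their medians were -0.28 (quartiles -0.78 and 0.47) and -2.04. These values argue against each of the 2 alone. Both at once, or a shift among kinds of basal cells, were not tested and stay open. The rise of Krt8 and Krt18 is unlikely to come from Merkel cells, as Krt20, Atoh1 and Isl1 reached at most 0.515 CPM in any knockout library. However, 5 of the 8 tested Merkel and simple epithelial markers were called higher, and not all of these are keratins. Calls of Isl1, Sox2 and Piezo2 were not part of this check, which was written after the data were seen. An altered state of the knockout keratinocytes is left as a hypothesis, with the sex make-up of the cultures untested against it for falls. The labels do not settle whether each genotype was 1 preparation of cells. If so, any difference between preparations, cell density included, would run with genotype for rises and falls alike. Separately prepared cultures of both genotypes, of the same sex and density, would be needed to decide.

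The third pattern is the rise of IFN response genes with no call among the tested interferon genes. The 20 type I and III ligand genes summed to 2.58 ± 0.235 CPM in wild type and 2.14 ± 0.497 CPM in knockout cells (n = 3 each), a ratio of 0.829, and the difference plus 2 SE corresponds to a ratio of 1.08. That margin is rough, since it rests on 3 libraries per group and on 159 to 318 counts per library, of genes that can share reads. No excess of ligand transcript in knockout cells was seen. The groups overlap, however, so whether such an excess at the time of collection accounts for the rise stays open. Expression before 8 h, secreted protein and sensitivity to interferon were not measured.

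Of the 10 splits of the 6 libraries into groups of 3, the real one called 8579 genes and the highest of the others called 0. So few splits cannot give a share under 0.05. Each other split also mixes the genotypes in both groups, so the large genotype difference adds to the spread there and leaves few calls possible. Their 0 calls are therefore no measure of calls made without a true difference. The prediction written for alleles linked to Cebpb was an excess of calls near it, and none was seen. Of the 100 tested genes nearest to Cebpb, 48% were called, at the 49.1 percentile of 15086 windows of neighbouring genes, with a median share of 49%. That share covers only effects of linked alleles on genes beside them. A linked allele that acts on genes elsewhere would leave no such excess, so the share cannot exclude it, nor effects of single linked alleles. In a hybrid background, pups could also differ at loci not linked to Cebpb, which was not tested.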
